A study of Mus musculus with 6 samples.

How the data were processed

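The samples were 6 distal colon libraries, 3 from wild-type and 3 from ChREBP knockout mice, with the group taken from the genotype label and the replicate number from the sample title. Per the labels' protocols, total RNA was extracted with Trizol, poly-A RNA was selected on oligo-dT beads, fragmented and copied into cDNA with random primers, and the libraries were amplified by PCR and circularised. The protocol names no step that marks strand, so reads of overlapping antisense genes cannot be told apart. The authors deposited 1 table of FPKM values with 2 decimals, 1 column per library and 19844 genes identified by NCBI gene numbers and RefSeq transcripts. The submitters' processing notes name HISAT2, RSEM and the mm39 build, and versions, filters and further normalization are not given in the sources used here. Counts were not analysed here, so the count models foreseen for that case were not run and limma on log values was the main test, as fixed for FPKM.

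Gene names and gene order came from the file and a RefSeq gene table of assembly GRCm38.p6, a different build, from which no coordinates are given. Of the 19844 identifiers, 19794 matched that table, and 27 symbols that a spreadsheet had turned into dates were restored from their identifiers. There were 63 genes at 1 FPKM or more that shared all 6 values with another gene. The table held 0 mitochondrially encoded genes and 0 immunoglobulin constant or T-cell receptor genes, so a list of mitochondrial genes could not be scored and those members are missing from the plasma and T cell lists.

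Depth was estimated from 348 short non-coding genes with 1 transcript of up to 150 bases, whose FPKM values step by whole reads. Fitting the depth per library and a shared length offset of 36 bases placed between 83.9% and 89.3% of the 112 to 133 tested values per library within 0.05 of a whole number of reads. The estimates were 18150000, 17700000 and 17750000 reads for wild-type replicates 1 to 3 and 18425000, 17975000 and 18175000 for knockout replicates 1 to 3. They are estimates from the values of short genes, and reads were not recovered for other genes. The sum of FPKM was between 439107 and 478500 per library, highest in knockout replicate 2.

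Genes at 1 FPKM or more in at least 3 of the 6 libraries were kept (13247 genes). log2(FPKM + 1) was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided, genotype as the sole term), with Benjamini-Hochberg adjustment and a threshold of 0.05. A second count required a 2-fold change. Standard errors and 95% intervals are limma's moderated values, and the median gene had a standard error of 0.133 and an interval half-width of 0.306 on the log2 scale. Replicates are labelled as separate samples, and the series design gives n = 3 per group of mice. Before the data were examined, the groups, the test, the filter, 37 gene lists, the alternatives and the rule for named genes were fixed. That rule takes Mlxipl, 12 genes in each direction (called genes first, then the smallest unadjusted p) with non-overlapping groups and a mean of at least 5 FPKM, leaving out predicted and immune receptor genes, up to 4 members of each list by smallest p, and a set of genes named in any case. Some list members that the rule names are left out of the text because they are withheld for evaluation. Genes singled out outside the rule are said to be so where they appear, apart from Xist, which was added once the Y-linked genes had been seen.

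Of 677 list entries 647 matched a gene, and 33 lists with at least 5 tested members were tested with camera (preset inter-gene correlation 0.01, two-sided, adjusted over lists), with camera using an estimated correlation and with fry beside it. No list was called with the estimated correlation (smallest adjusted p = 0.737) or by fry in 1 direction (smallest adjusted p = 0.734) or mixed (smallest adjusted p = 0.235). The residual degrees of freedom were 4. With the estimated correlation camera gave an adjusted p of 0.737 to the cell cycle list, called with the preset correlation, and to the uncalled ChREBP targets. A call lost there therefore does not tell lists apart. Y-linked, adipocyte and red blood cell lists had 4 tested members each and are given as values. The pipeline was tested on simulated data for this comparison: with 200 of 13247 genes changed in each of 20 simulations, drawn among genes above 5 FPKM, limma recovered 81.2% of 2-fold and 97.5% of 4-fold changes with a mean of 9.55 false calls. Camera called a list shifted by 0.5 on the log2 scale in 20 of 20 simulations, with a mean of 0.15 other lists called. Both simulations drew each gene independently, without structure shared between libraries, and the limma recovery depends on 200 genes being changed. The rates of recovery and of false calls therefore do not carry over to these data. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

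Alternatives were other pseudocounts (0.1 and 0.5), a looser and a stricter filter, 3 rescalings, 3 changes of the spread model, the replicate number as a block, leaving out each library, and for lists an estimated correlation, fry and ranks. Added after seeing the data were a test of protein-coding genes alone, a clock score as a covariate, and wild-type replicate 3 alone against the knockouts. The clock score is the mean log2 deviation of 10 output genes minus that of 4 genes of the Bmal1 limb, 14 genes in all.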

Results

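Distal colon was profiled by poly-A RNA sequencing in 6 C57BL6 mice on day 17 of a course of azoxymethane, a carcinogen, and dextran sulfate sodium, a polymer that injures the colon lining. The combination gives inflammation-driven colon tumours in mice. There were 3 wild-type mice and 3 knockouts for ChREBP, the carbohydrate response element binding protein, a glucose-responsive transcription factor encoded by Mlxipl. The series addresses whether ChREBP acts on colon carcinogenesis through the Wnt/beta-catenin pathway, and the design holds a single comparison, knockout against wild type. Expression was given as FPKM for 19844 genes, and between 13079 and 13253 genes per library reached 1 FPKM. Depth, estimated from the value of 1 read in short genes, lay between 17700000 and 18425000 reads per library, a ratio of 1.04. Group values are means ± SD of FPKM with n = 3 mice per group, and log2 fold changes are knockout minus wild type on the log2(FPKM + 1) scale, which understates the change of low genes. Adjusted p refers to limma with Benjamini-Hochberg adjustment over 13247 genes, and was 0.9995 for every tested gene named without another value.

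The labels give the sex of all 6 mice as female. The Y-linked genes were nevertheless expressed in all 6 libraries, with Ddx3y between 9.51 and 12.11 FPKM, Uty between 5.67 and 6.60, Kdm5d between 7.85 and 9.54 and Eif2s3y between 23.28 and 30.75. Xist, the RNA that silences an X chromosome in female cells, lay between 0.02 and 0.04 FPKM and was too low to be tested. Mean Ddx3y was 11.7 ± 0.754 in wild type and 9.82 ± 0.339 in knockout, and mean Eif2s3y was 26.9 ± 3.38 and 25.6 ± 2.49.

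Mlxipl (NCBI gene 58805), the targeted gene, was lower in each of the 3 knockout libraries than in any wild-type library, but its transcript was still present. Wild-type replicates 1 to 3 read 5.84, 7.49 and 7.27 FPKM (6.87 ± 0.896), and knockout replicates 1 to 3 read 3.40, 5.66 and 5.04 FPKM (4.70 ± 1.17). The knockout mean was 68.4% of the wild-type mean. The log2 fold change was -0.48 (SE 0.18), with a 95% interval of -0.89 to -0.07. For this gene, fixed in advance, the unadjusted limma p was 0.0258, but the difference did not pass the threshold over all genes (limma adjusted p = 0.9995). The lowest wild-type and highest knockout libraries were 0.18 FPKM apart, less than the pooled SD of 1.04. The values are per gene, so they do not say which exons the remaining reads cover, and the labels do not describe the deleted part. The partner Mlx was at 65.7 ± 3.93 FPKM in wild type and 61.9 ± 6.57 in knockout, and the paralog Mlxip at 29.6 ± 3.70 and 26.8 ± 1.22.

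Few transcripts passed the test of genotype. Of 13247 genes tested, limma called 2 at an adjusted p under 0.05, both microRNA genes with single reads, and no protein-coding gene was called in this model (smallest adjusted p among protein-coding genes 0.0574, for Glt1d1). The 2 called genes, singled out because there were so few, were Mir7045 (NCBI gene 102466272), which read 2.06, 2.12 and 2.10 FPKM in wild type and was listed at 0 in each knockout (adjusted p = 0.0109), and Mir7025 (NCBI gene 102465620), listed at 0 in each wild type and at 1.43, 1.47 and 1.45 FPKM in knockout (adjusted p = 0.0353). Each of those values above 0 equals 1 read at the estimated depth, so the reads of these 2 genes were equal within each group. Their adjusted p values therefore do not measure variation between mice and do not establish a difference of genotype. Leaving out a library left 1 called gene without wild-type replicate 1 and 0 without any other, with between 323 and 807 genes at an unadjusted p under 0.05 in limma. Both exceed the 2-fold threshold of 1 on the log2 scale, 1 gene higher and 1 lower. After rescaling each library to the same total the split was 1 higher and 2 lower. Restricting the test to protein-coding genes gave 0 calls in limma, with 430 genes at an unadjusted p under 0.05. In the main comparison 450 genes had an unadjusted p under 0.05, 225 higher and 225 lower, where 662 are expected by chance. The 3 knockout values lay wholly above or below the 3 wild-type values in 1149 genes, 8.67% against the 10% that chance gives. For 12846 genes (97.0%) the 95% interval of the log2 fold change lay within 2-fold in either direction on the log2(FPKM + 1) scale.

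Glt1d1 (NCBI gene 319804), a glycosyltransferase-domain gene on chromosome 5, as Mlxipl is, was singled out after its values were seen. It read 3.52 ± 0.332 FPKM in wild type and 0.810 ± 0.226 in knockout, a log2 fold change of -1.33 (SE 0.14) that missed the threshold (limma adjusted p = 0.0574). With other models of the spread it passed, at an adjusted p of 0.0318 without the mean-variance trend, 0.0425 with a robust prior and 0.0335 with array weights. Over the other alternatives its adjusted p lay between 0.0553 and 0.603. Between Glt1d1 and Mlxipl lie 46 tested genes in the gene order of the GRCm38.p6 RefSeq annotation, of which 0 had an unadjusted limma p under 0.05, against 3.39% of genes elsewhere. At that share few of the 46 would be expected, so a count of 0 does not show that the interval is unaltered. The fixed list of close neighbours of Mlxipl held 20 tested genes, 12 with positive and 8 with negative fold changes, and was not called (camera adjusted p = 0.327). Its members Bcl7b (18.5 ± 3.19 and 23.1 ± 2.45 FPKM in wild type and knockout) and Eln, the elastin gene (46.9 ± 13.3 and 63.2 ± 11.9), had the smallest p.

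No gene at 5 FPKM or more was called, so the genes of smallest p with groups that do not overlap are given as values. Those higher in the knockout libraries included Ankrd37, a hypoxia-inducible ankyrin-repeat gene, at 4.90 ± 3.18 FPKM in wild type and 18.6 ± 4.12 in knockout (log2 fold change 1.84, SE 0.34, limma adjusted p = 0.885). Efna1, the ephrin-A1 ligand, was at 39.7 ± 10.8 and 69.3 ± 12.2, Edn1, the endothelin-1 precursor, at 19.4 ± 2.76 and 35.2 ± 10.1, and Adm, the adrenomedullin precursor, at 4.09 ± 0.441 and 5.85 ± 0.422. The alpha-arrestin genes Arrdc2 (4.26 ± 0.582 and 7.15 ± 0.832) and Arrdc3 (15.9 ± 3.05 and 24.8 ± 3.49) were placed alike, as was Pnrc1, a nuclear receptor coregulator (32.1 ± 3.57 and 51.0 ± 7.66). Sprr1a, a cornified-envelope gene, was at 8.22 ± 1.30 and 18.6 ± 7.05, and the mitotic cyclin gene Ccnb2 at 11.9 ± 0.628 and 17.6 ± 3.33. Also higher were the tight junction gene Cldn23 (14.8 ± 0.434 and 19.3 ± 0.647), Leng9 (17.5 ± 1.43 and 24.8 ± 3.18) and Lrrc66 (15.5 ± 0.536 and 19.8 ± 1.001).

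The genes of smallest p lower in the knockout libraries were led by Usp2, a deubiquitinase gene with daily rhythms in many tissues, at 13.1 ± 3.68 FPKM in wild type and 4.75 ± 0.700 in knockout (log2 fold change -1.27, SE 0.21, limma adjusted p = 0.591). Fam102a was at 54.4 ± 0.430 and 35.7 ± 3.77 (adjusted p = 0.591), the potassium channel subunit gene Kcne3 at 125 ± 1.87 and 88.7 ± 5.51 (adjusted p = 0.885), and Ang4, an antimicrobial ribonuclease of secretory cells, at 15.1 ± 8.57 and 2.48 ± 0.803 (adjusted p = 0.885). Ang4 has close paralogs with which reads may be shared, as does the pseudogene Marcksl1-ps4 (19.0 ± 2.45 and 12.2 ± 0.285, adjusted p = 0.889). Cry2, a repressor of the circadian clock, was at 8.99 ± 1.76 and 4.88 ± 1.16, the activin receptor gene Acvr1b at 33.0 ± 1.20 and 23.8 ± 2.68, and the nuclear long non-coding RNA Malat1 at 84.2 ± 6.93 and 59.2 ± 6.45. Plekhg6 (8.95 ± 1.51 and 5.03 ± 0.726), AA986860 (8.10 ± 1.37 and 5.02 ± 0.420), Fam46c (8.33 ± 1.24 and 5.32 ± 0.496) and the sialyltransferase gene St6galnac4 (18.7 ± 1.17 and 12.7 ± 2.21) complete the group. Clock genes also differed between libraries, and with a clock score in the fit the log2 fold changes of Usp2, Cry2 and Ang4 were nearer 0 (-1.01, -0.58 and -1.65), and with wild-type replicate 3 as the sole wild type they were -0.805, -0.493 and -1.22. With the clock score those of AA986860 (-0.735), Ankrd37 (2.29), Efna1 (1.08) and Arrdc3 (0.81) were farther from 0, and Efna1 was at 1.28 with wild-type replicate 3 alone.

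Wnt/beta-catenin target genes leaned lower in the knockout by a small amount. Of 17 tested targets 14 had negative and 3 positive log2 fold changes, with a median of -0.12, and the list was called lower by camera with its preset correlation (adjusted p = 0.0032, over 33 lists). That call was lost with an estimated correlation (adjusted p = 0.737) and without knockout replicate 2 (adjusted p = 0.0648). Camera with the estimated correlation gave the same adjusted p to lists that were never called, so that loss does not tell lists apart. Fry did not call the Wnt targets either (adjusted p = 0.734 in 1 direction and 0.329 mixed). The number of lists called with the preset correlation was not particular to genotype, a limit on the calls here and below. Of 10 splits of the 6 libraries into 3 and 3, the genotype split included, 5 called at least 11 lists. The splits were compared by this count alone, so they do not say whether any single list call is particular to genotype. No target passed the test singly, either over all genes or adjusted over the list alone, and for all 17 the 95% interval lay within 2-fold on the log2(FPKM + 1) scale, which does not exclude a 2-fold fall in FPKM for low genes such as Lgr5 and Ascl2. Ascl2, a transcription factor of intestinal stem cells, was at 5.44 ± 0.824 FPKM in wild type and 3.43 ± 0.325 in knockout (log2 fold change -0.54, SE 0.13), the stem cell receptor Lgr5 at 2.64 ± 0.728 and 1.75 ± 0.110, and the Wnt-receptor ligase Rnf43 at 13.5 ± 0.649 and 11.5 ± 0.752. Axin2, a direct feedback target of the pathway, was at 11.6 ± 0.312 and 10.9 ± 1.36, a log2 fold change of -0.09 with a 95% interval of -0.34 to 0.17. Myc was at 21.3 ± 2.27 and 18.5 ± 1.93 (interval -0.46 to 0.08), Ccnd1, the cyclin D1 gene, at 30.9 ± 2.11 and 27.1 ± 4.28 (interval -0.49 to 0.09), and Sox9 at 21.3 ± 3.33 and 17.1 ± 2.36 (interval -0.63 to 0.03). Cd44 was at 17.2 ± 2.48 and 17.5 ± 2.29, and the sign of its difference changed when libraries were rescaled to the same total.

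**Figure D1:**
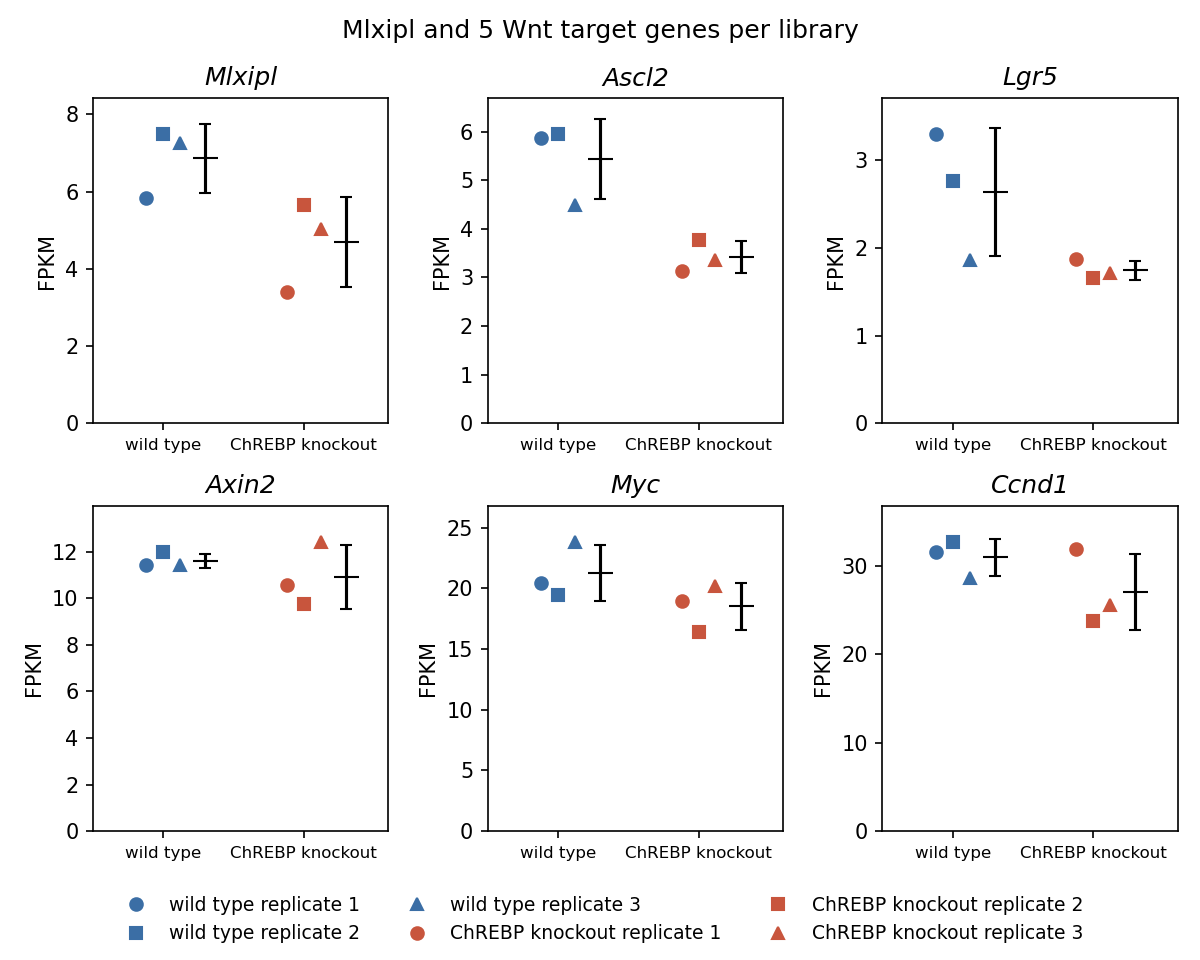
FPKM per library (vertical axes, each starting at 0) of Mlxipl and 5 Wnt target genes in 3 wild-type (blue) and 3 ChREBP knockout (red) mice, with marker shape giving the replicate number and black bars giving mean ± SD. Mlxipl lies between 5.84 and 7.49 in wild type and between 3.40 and 5.66 in knockout, and the groups overlap for Lgr5, Axin2, Myc and Ccnd1 but not for Ascl2.

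The components of the Wnt pathway, as opposed to its targets, were not called. Of 32 tested components 17 had positive and 15 negative fold changes, with a median of 0.01, a mean of -0.02 and a camera direction of lower (adjusted p = 0.424). Ctnnb1, which encodes beta-catenin, was at 225 ± 7.55 FPKM in wild type and 222 ± 28.1 in knockout (95% interval of the log2 fold change -0.30 to 0.23), and Apc, the scaffold of its destruction complex, read 15.98, 12.10 and 16.92 in knockout against 15.9 ± 1.28 in wild type (interval -0.41 to 0.23). The ligand gene Wnt2b was at 4.89 ± 0.662 and 3.06 ± 0.475 and Dvl3 at 19.98 ± 1.03 and 16.8 ± 2.09. Intestinal stem cell markers, which share Ascl2, Lgr5, Axin2, Sox9 and Tnfrsf19 with the target list, had 11 negative and 2 positive fold changes among 13 tested (median -0.11). They were called lower by camera (adjusted p = 0.00427), and the call was lost with an estimated correlation (adjusted p = 0.737). It was also lost without knockout replicate 1 (adjusted p = 0.0619) or knockout replicate 2 (adjusted p = 0.106). The cell cycle kinase gene Cdk6, a further marker, was at 4.33 ± 0.717 and 3.29 ± 0.466.

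ChREBP target genes did not move as a group. Of 20 tested targets 10 had positive and 10 negative log2 fold changes, with a median of -0.01, and camera did not call the list (adjusted p = 0.613). No target was called over all genes or adjusted over the list alone. For all 20 the 95% interval lay within 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes such as Acacb. Mlxipl transcript stayed at 68.4% of the wild-type mean in the knockout libraries, and these values do not show how far ChREBP itself was lost. Pklr, the pyruvate kinase gene used as a classical readout of ChREBP in liver, was at 32.5 ± 1.15 FPKM in wild type and 34.3 ± 2.02 in knockout, and Txnip, a redox regulator induced by glucose, at 342 ± 86.5 and 322 ± 68.6. Among the fatty acid synthesis genes, Fasn was at 23.2 ± 3.69 and 22.2 ± 6.76, Scd1 at 21.0 ± 3.48 and 22.6 ± 2.31, Acly at 112 ± 16.0 and 105 ± 23.5, Acaca at 11.4 ± 0.736 and 11.7 ± 1.37 and Acacb at 1.45 ± 0.208 and 1.79 ± 0.593. The difference of Acaca changed sign when libraries were rescaled to the same total. The list of ChREBP relatives and lipogenic regulators had 5 positive and 5 negative members among 10 tested (camera adjusted p = 0.596), with the fatty acid sensor Ppara at 1.82 ± 0.406 and 1.38 ± 0.412.

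Glycolysis and cholesterol synthesis genes were called higher in the knockout with the preset correlation. For glycolysis 18 of 20 tested genes had positive fold changes (median 0.10, camera adjusted p = 0.0156, but adjusted p = 0.737 with an estimated correlation). Hexokinase 2, Hk2, was at 34.2 ± 8.14 FPKM in wild type and 51.7 ± 13.5 in knockout, whereas Hk1 was at 80.7 ± 3.44 and 70.6 ± 8.08. The lactate exporter Slc16a3 read 14.81, 6.56 and 6.87 in knockout replicates 1 to 3 against 5.74 ± 0.963 in wild type. For cholesterol synthesis 21 of 23 genes had positive fold changes (median 0.16, camera adjusted p = 0.00427, but adjusted p = 0.737 with an estimated correlation). Pmvk was at 14.5 ± 1.64 and 17.9 ± 1.66, Fdft1, the squalene synthase gene, at 26.0 ± 0.351 and 30.1 ± 2.55, and Cyp51 at 28.4 ± 4.44 and 33.1 ± 2.21. The glycolysis call was lost without wild-type replicate 2 (adjusted p = 0.05), wild-type replicate 3 (0.107), knockout replicate 1 (0.17) or knockout replicate 3 (0.18), and the cholesterol call without wild-type replicate 3 (0.314) or knockout replicate 1 (0.495).

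Other parts of energy metabolism were not called. Fatty acid oxidation and uptake had 8 positive and 11 negative members among 19 tested (camera adjusted p = 0.176), with the carnitine palmitoyltransferase genes Cpt1a at 71.2 ± 9.67 and 58.2 ± 2.81 FPKM and Cpt2 at 30.9 ± 2.75 and 26.2 ± 2.87. Oxidative phosphorylation had 20 positive and 14 negative members among 34 (camera adjusted p = 0.925), and its direction changed with each of 3 rescalings. It was called lower without knockout replicate 2 (adjusted p = 0.0269), and fatty acid oxidation was called lower without wild-type replicate 2 (adjusted p = 0.00378). The respiratory chain genes Ndufs7 and Atp5d were at 63.6 ± 3.96 and 72.8 ± 5.74 and at 339 ± 13.1 and 366 ± 25.2.

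Cell cycle genes gave the smallest list p. Of 34 tested genes 30 had positive fold changes, with a median of 0.20, and camera called the list higher (adjusted p = 2.78e-05, but adjusted p = 0.737 with an estimated correlation). Ube2c, which acts at mitotic exit, was at 38.6 ± 4.96 FPKM in wild type and 54.1 ± 10.6 in knockout, the centromeric histone Cenpa at 9.30 ± 1.10 and 13.5 ± 2.90, and the proliferation marker Mki67 at 30.2 ± 3.28 and 34.6 ± 7.54. Knockout replicate 1 stood highest, with a mean deviation of 0.41 on the log2 scale from the average of the 6 libraries, and wild-type replicate 3 lowest at -0.32. The call was lost without knockout replicate 1 (adjusted p = 0.495) or wild-type replicate 3 (adjusted p = 0.0623).

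Acute inflammation genes were called higher, and the difference lay mainly in knockout replicate 1. Of 17 tested genes 14 had positive fold changes (median 0.24, camera adjusted p = 0.0294, but adjusted p = 0.737 with an estimated correlation). The neutrophil-attracting chemokine Cxcl5 read 13.83, 4.05 and 2.43 FPKM in knockout replicates 1 to 3 against 1.86 ± 0.251 in wild type, and the granulocyte protein gene S100a9 read 6.55, 1.99 and 1.31 against 1.11 ± 0.235. Tnf was at 2.16 ± 0.465 and 4.27 ± 1.76, while Il1b was at 2.08 ± 1.08 and 1.48 ± 0.730, and Il6, too low to be tested, was listed at 0 in 5 libraries and at 0.05 in the other. The call was lost without wild-type replicate 1 (adjusted p = 0.152), wild-type replicate 2 (0.0753), knockout replicate 1 (0.495) or knockout replicate 2 (0.222). Neutrophil markers, which include S100a8 (0.887 ± 0.185 and 2.68 ± 2.91) and S100a9, had 5 of 5 positive members and were not called (camera adjusted p = 0.142), but were called higher without knockout replicate 3 (adjusted p = 0.00601).

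Interferon response genes were called lower, with 26 negative and 4 positive fold changes among 30 tested (median -0.27, camera adjusted p = 0.00427, but adjusted p = 0.737 with an estimated correlation). The chemokine Cxcl9 was at 3.33 ± 1.69 FPKM in wild type and 1.94 ± 0.653 in knockout and the guanylate-binding protein gene Gbp7 at 8.25 ± 2.56 and 6.46 ± 1.44, whereas Irf1 was at 74.0 ± 12.1 and 83.3 ± 1.92. Wild-type replicate 2 stood highest, by 0.69 on the log2 scale, and knockout replicate 3 lowest, at -0.57. Without wild-type replicate 2 the direction turned (adjusted p = 0.803), and without knockout replicate 3 the call was lost (adjusted p = 0.946). Antigen presentation by MHC class II had 7 negative members among 8 (camera adjusted p = 0.28), with H2-Eb1 at 78.9 ± 11.2 and 69.8 ± 15.2 and H2-Aa at 204 ± 26.0 and 187 ± 54.9. It was called lower without wild-type replicate 3 (adjusted p = 0.00143) or knockout replicate 2 (adjusted p = 0.00282).

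Markers of lymphoid cells other than B cells were called lower. T and NK cell markers had negative fold changes in 10 of 10 tested genes (median -0.16, camera adjusted p = 0.0217, but adjusted p = 0.737 with an estimated correlation). The filter kept these 10 of 20 matched members. Among them were Cd4 (5.82 ± 0.786 and 4.41 ± 1.81 FPKM), the kinase gene Zap70 (1.10 ± 0.0436 and 0.857 ± 0.0551) and Lck (3.32 ± 0.947 and 2.62 ± 0.594). Zap70 reached 1 FPKM in the wild-type libraries alone, so the filter favoured its negative sign. Plasma cell markers had negative fold changes in 5 of 6 (median -0.52, camera adjusted p = 0.0156, but adjusted p = 0.737 with an estimated correlation). Knockout replicates 1 to 3 read 173.31, 361.40 and 110.51 for Jchain, the joining chain of secreted antibodies, against 312 ± 29.0 in wild type. Derl3 was at 7.34 ± 0.630 and 4.65 ± 2.96, and Mzb1 at 17.7 ± 3.04 and 11.7 ± 5.54. The T and NK call was lost without wild-type replicate 2 (adjusted p = 0.39), knockout replicate 1 (0.0815) or knockout replicate 3 (0.451), and the plasma cell call without wild-type replicate 3 (0.133) or knockout replicate 3 (0.576). B cell markers, with 10 positive and 3 negative members (camera adjusted p = 0.571), followed single libraries, with Fcer2a at 5.68, 10.77 and 1.42 in wild type and 6.25 ± 1.47 in knockout, and Blk at 2.62 ± 1.96 and 2.81 ± 0.843. The B cell list was called lower without wild-type replicate 3 (adjusted p = 3.01e-09) and higher without wild-type replicate 2 (adjusted p = 0.000123). Its direction also turned without knockout replicate 1 (adjusted p = 0.737). Macrophage and monocyte markers had 13 negative members among 17 (camera adjusted p = 0.148), with Ly6c2 at 23.8 ± 1.85 and 17.3 ± 9.54 and Cd14 at 26.9 ± 2.15 and 30.7 ± 7.10. They were called lower without wild-type replicate 1 (adjusted p = 0.0246), wild-type replicate 2 (0.00752) or knockout replicate 2 (1.87e-06), and turned without wild-type replicate 3 (0.314) or knockout replicate 3 (0.911).

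Markers of secretory epithelial cells were called lower, and both lists leaned on knockout replicate 3. Goblet cell markers had negative fold changes in 13 of 15 tested genes (median -0.14, camera adjusted p = 0.00126, but adjusted p = 0.737 with an estimated correlation), and enteroendocrine markers in 10 of 10 (median -0.21, camera adjusted p = 0.000762, but adjusted p = 0.737 with an estimated correlation). Ang4 was the single gene of any list that passed when adjusted over the list alone. Clca1, a goblet cell secretory protein gene, was at 2497 ± 411 FPKM in wild type and 1697 ± 177 in knockout, and Bcas1 at 80.1 ± 3.53 and 69.9 ± 11.4. Muc2, the main gel-forming mucin, was at 703 ± 46.2 in wild type and read 928.52, 808.67 and 427.29 in knockout replicates 1 to 3. Of the enteroendocrine genes, the serotonin synthesis enzyme Tph1 was at 7.22 ± 1.74 and 5.18 ± 0.536, and the granins Chga and Chgb at 39.6 ± 3.41 and 33.5 ± 2.67 and at 52.8 ± 8.49 and 43.2 ± 4.53. Without knockout replicate 3 both calls were lost (adjusted p = 0.911 for goblet cells and 0.395 for enteroendocrine cells). That library stood at -0.59 and -0.47 on the log2 scale for the secretory lists and at 0.59 for smooth muscle.

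**Figure D2:**
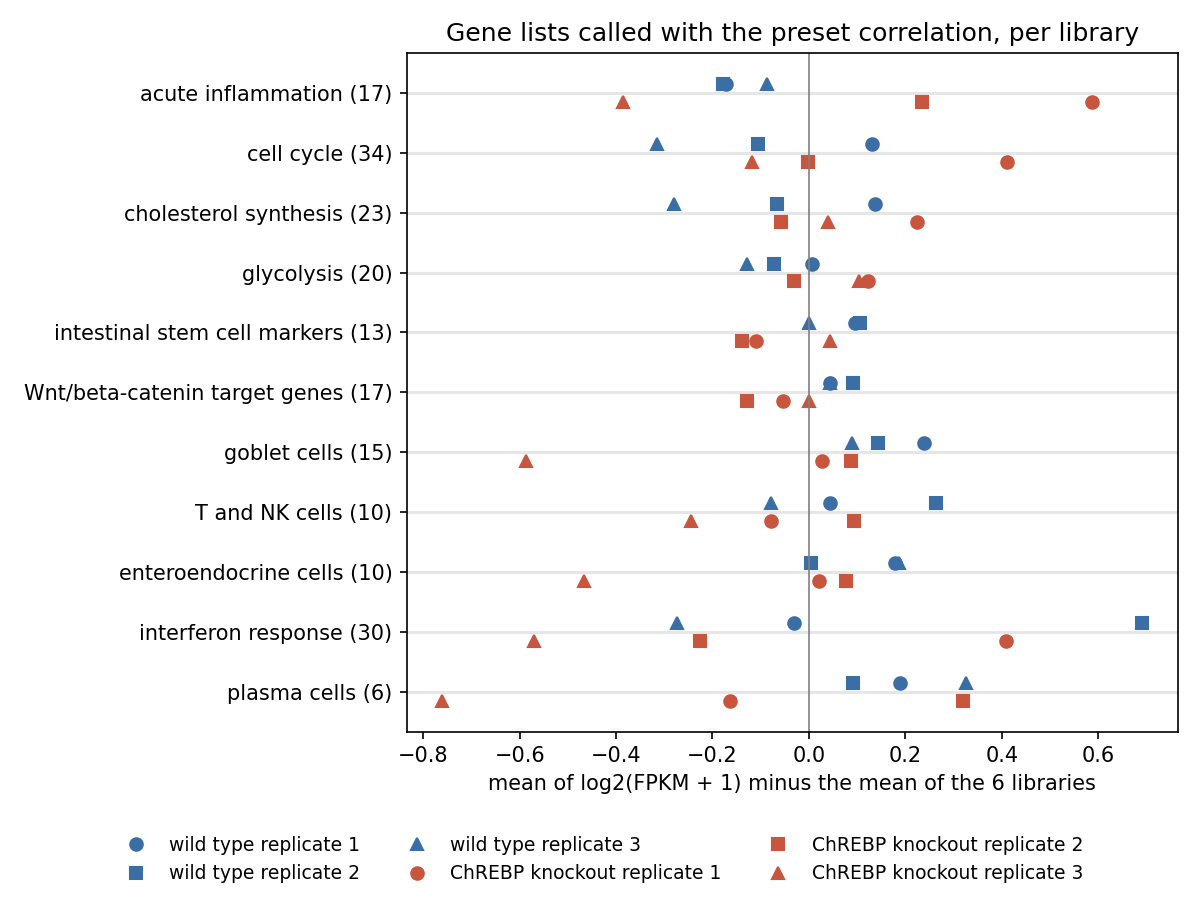
Mean deviation of each library from the average of the 6 libraries, on the log2(FPKM + 1) scale (horizontal axis), for the 11 gene lists called by camera with its preset correlation (vertical axis, number of tested genes in brackets). Knockout replicate 3 (red triangle) lies at -0.59 for goblet cells and knockout replicate 1 (red circle) at 0.41 for cell cycle, apart from the remaining points of those lists.

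The remaining epithelial and tissue lists were not called. Absorptive colonocyte markers had 9 positive and 10 negative members (camera adjusted p = 0.424), with the sulfate transporter Slc26a2 at 170 ± 38.4 and 121 ± 43.3 FPKM and Cdhr5 at 343 ± 25.5 and 392 ± 13.8. Tuft cell markers had 4 negative of 5 (camera adjusted p = 0.327), with Ptgs1 at 13.6 ± 0.401 and 12.6 ± 0.801 and Dclk1 at 3.11 ± 0.457 and 2.75 ± 0.343. Smooth muscle had 14 positive of 15 (camera adjusted p = 0.0866), with Smtn at 50.6 ± 6.06 and 66.6 ± 22.3 and Lmod1 at 20.01 ± 2.19 and 26.0 ± 11.2. Fibroblast and matrix genes had 16 positive of 20 (camera adjusted p = 0.0856), among them the collagen genes Col1a1 (90.3 ± 5.38 and 107 ± 14.4) and Col6a3 (16.4 ± 1.97 and 19.6 ± 3.25). Enteric neurons and glia had 9 positive of 14 (camera adjusted p = 0.197), with the tachykinin gene Tac1 at 15.2 ± 1.17 and 18.7 ± 1.33. Endothelial markers had 9 positive of 14 (camera adjusted p = 0.488), with Cldn5 at 3.60 ± 0.379 and 5.13 ± 0.416 and Kdr at 4.59 ± 0.297 and 3.59 ± 1.07. Squamous genes of the anal canal had 4 positive of 6 (camera adjusted p = 0.0766). Of these, 2 genes at low levels were Krt10 (0.737 ± 0.136 and 1.11 ± 0.0751) and Sbsn (0.863 ± 0.244 and 1.39 ± 0.327). Krt10 reached 1 FPKM in the knockout libraries alone, so the filter favoured its positive sign. Posterior Hox and position genes had 4 positive of 7, with a positive median and mean but a camera direction of lower (adjusted p = 0.77). Hoxa13 was at 17.04 ± 0.912 and 15.3 ± 1.06 and Hoxd12 at 3.93 ± 1.18 and 4.98 ± 1.93. Some of these lists were called higher when a library was left out: without knockout replicate 2 smooth muscle (adjusted p = 0.000993), fibroblasts (0.00488), endothelium (0.00649), enteric neurons and glia (0.0321) and squamous genes (0.0366), without wild-type replicate 2 smooth muscle (0.00262) and squamous genes (0.00385), without knockout replicate 1 smooth muscle (0.0049), and without wild-type replicate 3 fibroblasts (0.00143).

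Stress and injury programmes gave no call with all 6 libraries in the chosen model. Genes of regenerative fetal-like epithelium had 6 positive and 6 negative members, a median of 0.01, a mean of -0.04 and a camera direction of lower (adjusted p = 0.77), with the interleukin-1 antagonist Il1rn at 46.6 ± 2.31 and 57.8 ± 3.19 FPKM and Ctgf at 30.0 ± 5.12 and 20.3 ± 7.29. The unfolded protein and amino acid stress list had 11 negative of 14 (camera adjusted p = 0.142, called lower at 0.00217 without wild-type replicate 3 at 0.000396 without knockout replicate 1 and at 0.00112 with array weights), with Herpud1 at 105 ± 30.0 and 85.0 ± 8.82 and Xbp1 at 124 ± 13.8 and 110 ± 17.7. Targets of p53 had 11 negative of 17 (camera adjusted p = 0.314), with Trp53inp1 at 29.1 ± 1.37 and 23.3 ± 3.90 and Gdf15 at 2.88 ± 0.348 and 1.95 ± 0.679. Immediate early and heat shock genes had 9 positive of 15 (camera adjusted p = 0.646), with Jun at 30.8 ± 4.22 and 39.6 ± 5.19 and Nr4a1 at 16.1 ± 11.4 and 7.59 ± 2.54. Lists with 4 tested genes were given as values only. Among adipocyte genes Cfd was at 2.46 ± 2.03 and 5.33 ± 3.16 and Lipe at 4.02 ± 0.110 and 4.14 ± 0.269. Among red blood cell genes Hbb-bt was at 4.13 ± 3.42 and 5.33 ± 2.11 and Hba-a2 at 21.7 ± 6.14 and 23.8 ± 5.37, globins that share reads with near-identical copies. Of the 22 lists that were not called, 12 were called in at least 1 of the 6 fits that left out a library.

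The libraries did not separate by genotype. The first 2 principal components held 32.7% and 21.4% of the variance, and the first placed wild-type replicates 1 and 2 (-10.8 and -9.08) beside knockout replicate 1 (-19.9), and wild-type replicate 3 (17.3) beside knockout replicates 2 (14.7) and 3 (7.75). Pearson correlations between libraries, across genes, lay between 0.9762 and 0.9898. Genes of the circadian clock, singled out after their values were seen, differed between wild-type mice. Dbp, a clock output transcription factor, read 57.41, 43.06 and 0.95 FPKM in wild-type replicates 1 to 3 and 5.77, 0.94 and 6.14 in knockout replicates 1 to 3. Tef read 46.58, 38.92 and 5.36 against 12.11, 5.53 and 12.70, and Per2 read 21.70, 16.13 and 5.75 against 7.68, 3.87 and 7.06. The opposite limb of the clock was placed the other way, with Arntl, which encodes BMAL1, at 6.33, 8.25 and 26.90 against 17.20, 26.30 and 19.07, Npas2 at 3.80, 7.12 and 17.29 against 14.08, 20.75 and 13.19, and Nfil3 at 1.02, 1.22 and 4.89 against 3.71, 4.08 and 3.69. Nr1d1 was likewise low in wild-type replicate 3, but knockout replicates 1 and 3 lay nearer wild-type replicates 1 and 2: it read 77.67, 94.62 and 16.13 against 65.33, 27.65 and 80.01. Clock differed less and lay between 16.90 and 23.25 in all 6 libraries. None of these genes passed the genotype test.

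**Figure D3:**
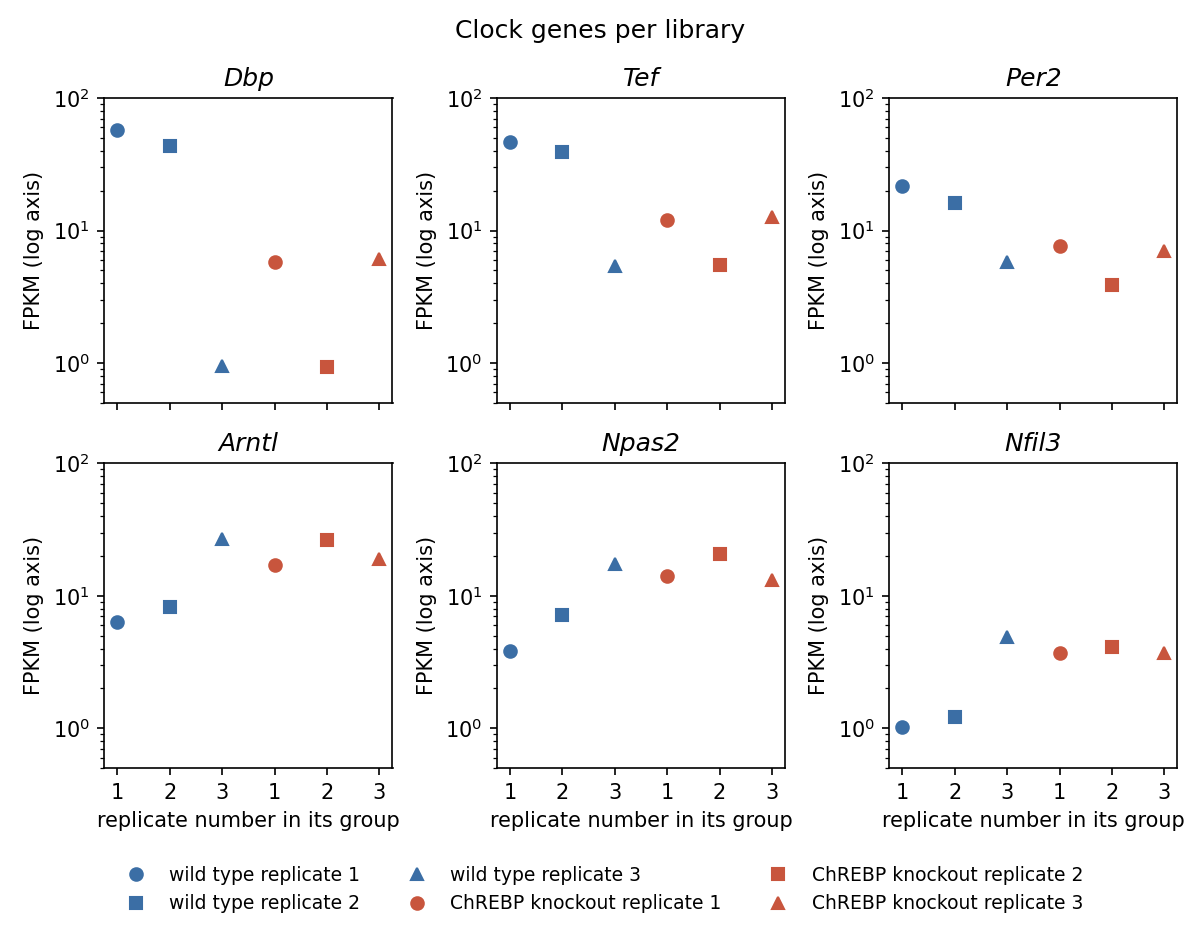
FPKM per library (vertical axes, log scale) of 6 clock genes by replicate number within group (horizontal axes), for wild type (blue) and ChREBP knockout (red). Wild-type replicates 1 and 2 show Dbp at 57.41 and 43.06 and Arntl at 6.33 and 8.25, while wild-type replicate 3 shows 0.95 and 26.90.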

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

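The tests of protein-coding genes alone, with a clock score as a covariate and of wild-type replicate 3 alone against the knockouts were chosen only after the result was seen. The planned count-based alternatives were not run because the table holds FPKM. Mlxipl was lower in the knockout under every alternative run, with log2 fold changes between -0.603 and -0.304 when a library was left out, and was called under none. Of 2408 values of 122 named genes under the alternatives, 2342 kept direction and side of the threshold, 18 lost a call, 3 gained a call and 45 changed direction. The 3 gained calls are Glt1d1, whose log2 fold change stayed at -1.33, without the mean-variance trend, with the robust prior and with array weights. Lists changed direction in 19 of 198 values with a library left out and in 22 of 555 others. Where a result changed, the cause was not tested, except that a stricter filter and protein-coding genes alone remove the 2 called microRNA genes. Depth limits the shortest genes, since the 2 called microRNA genes hold 1 read in each library where they are seen.

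At 5 FPKM or more 0 genes were called by limma, 0 at 2-fold (321 at an unadjusted p under 0.05), and 7 lists, with the stem cell call lost (0.0853) and the called lists acute inflammation, T and NK cells and plasma cells left with too few genes to be tested. With a pseudocount of 0.1 acute inflammation lost its call (0.0632) and squamous genes gained one (0.0419), as they did rescaled to the same total (0.0343), and quantile normalization lost glycolysis (0.0707). With protein-coding genes only 0 and 0 genes were called (430 at an unadjusted p under 0.05), and with the clock score 0 and 0 (930). Rescaled to the same total, Cd44 was -0.00265 and Acaca -0.0021, and oxidative phosphorylation turned at an adjusted p of 0.835, at 0.973 with size factors, 0.576 with quantile normalization and 0.971 on ranks. With array weights Cd44 was -0.0302, Txnip 0.0275, Fcer2a -0.144 and Blk -0.151, and lists turned for oxidative phosphorylation (0.626), regenerative epithelium (0.995), B cells (0.0643) and posterior Hox genes (0.648). Cholesterol synthesis (0.0888) and acute inflammation (0.191) lost their calls there, and MHC class II (0.00131), unfolded protein stress (0.00112), fibroblasts (0.00365), smooth muscle (0.00112) and enteric neurons and glia (0.0401) gained one. With a replicate block 0 and 0 genes were called (504 at an unadjusted p under 0.05), posterior Hox genes turned (0.802), and unfolded protein stress (0.0315) and smooth muscle (0.0481) were called. The main fit held no block, as fixed beforehand, because no label says that the replicate numbers pair animals. The correlations of deviations between equal replicate numbers were 0.27, -0.0963 and 0.0629, and those between unequal numbers lay between -0.289 and 0.253. With an estimated correlation 0 lists were called (Wnt targets 0.737), and by fry 0 (Wnt targets 0.734, regenerative epithelium 0.954).

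With the clock score Cd44 was -0.00594, Fasn 0.117, Acly 0.0596, Herpud1 0.00702, Hbb-bt -0.204 and Hba-a2 -0.11, and lists turned for ChREBP targets (0.814), oxidative phosphorylation (0.818), MHC class II (0.78), unfolded protein stress (0.818) and colonocytes (0.892). Calls were lost for stem cell markers (0.184), acute inflammation (0.78), interferon response (0.818) and T and NK cells (0.283), and gained for fatty acid oxidation (0.0366), macrophages (8.65e-07) and B cells (5.3e-09). With wild-type replicate 3 alone, assumed to vary like the other group, Fasn was 0.159, Acly 0.056, Cxcl9 0.155, Gbp7 0.00115, H2-Eb1 0.058, Herpud1 0.14, Xbp1 0.00121, Eif2s3y 0.0415, Lck 0.117, Hoxd12 -0.0417, Hbb-bt -0.58 and Hba-a2 -0.179. There the calls of Wnt targets (0.0713), stem cell markers (0.32), acute inflammation (0.766) and T and NK cells (0.861) were lost, calls were gained for fatty acid oxidation (0.0189), macrophages (5.23e-06), B cells (3.4e-23) and squamous genes (0.0464), and lists turned for ChREBP targets (0.829), interferon response (0.208, its call lost), MHC class II (0.0391, called higher), unfolded protein stress (0.379), colonocytes (0.771), fibroblasts (0.484) and endothelium (0.82).

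Leaving out each library in turn gave between 0 and 1 called genes, 0 and 1 at 2-fold, and between 6 lists (without knockout replicate 3) and 16 (without knockout replicate 2). Log2 fold changes that crossed 0 ranged from -0.121 to 0.0622 for Ctnnb1, -0.181 to 0.045 for Apc, -0.0757 to 0.121 for Cd44, -0.293 to 0.0923 for Txnip, -0.307 to 0.11 for Fasn, -0.0181 to 0.212 for Scd1, -0.0357 to 0.114 for Acaca, -0.267 to 0.0542 for Acly, -0.256 to 0.303 for Muc2, -0.133 to 0.0349 for Eif2s3y, -0.31 to 0.831 for Fcer2a, -0.284 to 0.61 for Blk, -0.0274 to 0.522 for Lmod1 and -0.101 to 0.334 for Hba-a2. Adjusted p ranged from 0.00248 to 0.0648 for Wnt targets, 0.133 to 0.935 for Wnt components, 0.314 to 0.819 for ChREBP targets, 0.0269 to 0.993 for oxidative phosphorylation, 5.15e-09 to 0.946 for interferon response, 0.00143 to 0.911 for MHC class II, 0.24 to 0.865 for regenerative epithelium, 0.228 to 0.865 for colonocytes, 1.87e-06 to 0.911 for macrophages, 3.01e-09 to 0.737 for B cells, 0.000993 to 0.721 for smooth muscle, 0.00649 to 0.956 for endothelium and 0.299 to 0.956 for posterior Hox genes.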

Other observations

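The tests of clock phase, of a knockout effect on the clock, of the sex label and of the Mlxipl transcript were chosen only after the result was seen, while the splits of the libraries were planned. For the top genes with a clock score, the bounds were set before that result was seen, although the score was added after seeing the data.

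The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2 genes and the highest other split 5, with 5 of 10 splits calling at least as many as the real one, and the same numbers, 5 of 10 with a highest of 5, hold for changes of 2-fold or more. For gene lists the real split called 11 and the highest other 14, with 5 of 10 splits calling at least as many. The number of list calls with the preset correlation thus cannot be told apart from the numbers that other groupings of these libraries give. Which lists the other splits called was not compared. Wild-type replicates 1 and 2 with knockout replicate 1 against the rest gave 1700 genes at an unadjusted limma p under 0.05, against 450 for genotype, which points to a structure of the samples other than genotype. That split had the highest such count of the 10 and is the grouping that the first principal component already showed, so it adds no separate evidence.

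Clock genes differed between the wild-type libraries. Whether the libraries were collected at different clock phases cannot be told apart from another shift of the clock: the means of its 2 limbs were opposed across the 6 libraries (Pearson r = -0.978), but these genes were listed after their values were seen, and opposed limbs would follow from any such shift. A shift by the ChREBP knockout alone was predicted to place the 3 wild-type clock scores above the 3 knockout scores. Wild-type replicate 3 instead had a score of -1.53, below all 3 knockout scores (-0.521, -1.36 and -0.274). That library is 1 sample and its clock genes prompted the test, so its score restates what had been seen and does not decide the question. Whether clock phase accounts for the top named genes cannot be told apart: their absolute log2 fold changes kept a median ratio of 0.982 with the clock score in the fit. That lies above 0.8, the bound set beforehand as speaking against this explanation. These genes were picked for groups that do not overlap, which leaves the score little to remove, so the bound could not decide the question. Collection times were not used here, and a ChREBP effect on the clock in addition to phase stays open.

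Y-linked genes were expressed in libraries labelled female. All 4 Y-linked genes reached 1 FPKM and Xist stayed under it in 6 of 6 libraries, consistent with male animals and a sex label that is wrong. Male RNA mixed into female samples is argued against by Xist, whose highest value was 0.04 FPKM, since female cells would bring their own. No biological explanation was tested.

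Mlxipl transcript remained in libraries labelled ChREBP knockout, at 68.4% of the wild-type mean. An allele that leaves part of the transcript countable may be the reason, and it cannot be told apart from a transcript left whole, because the values are per gene and not per exon. Swapped labels between the groups also cannot be told apart, since the lowest wild-type library was 0.18 FPKM above the highest knockout library, less than the pooled SD of 1.04. Other reasons for the remaining transcript were not examined.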
